A study of Homo sapiens with 15 samples.

How the data were processed

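Polyadenylated RNA was sequenced from 15 cultures of SH-SY5Y, a human neuroblastoma cell line, in 3 groups of 5: control, ethanol and withdrawal. Per the labels' protocols, libraries were made with the KAPA mRNA Hyper Prep kit and read as 75-base pairs on an Illumina HiSeq instrument. Per the submitters' processing notes, FastQC 0.11.5, STAR, featureCounts of Subread 1.5.1 and edgeR were used, with the genome build GRCh38 (hg38). The annotation and the strand setting of the counting were not given in the sources used here. Reads of antisense, overlapping or near-identical genes could therefore not be told apart, and values of such genes are uncertain.

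The authors deposited CPM (read counts scaled to library totals) for 14379 genes in 15 libraries, each column taken relative to the total over the listed genes. The mean CPM of the lowest listed gene was 0.348. In all 15 columns 100% of the values were whole multiples of the value of 1 read, within 0.001 reads, so that the counted reads could be recovered. Totals lay between 17.7 and 23 M reads (M for mega), with means of 21 ± 2.02 M for control, 19.8 ± 0.634 for ethanol and 20.9 ± 0.999 for withdrawal (SD, n = 5). At these depths 3 reads correspond to between 0.131 and 0.169 CPM, which covers counting error only.

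Groups and replicate numbers were taken from the labels, in which the replicate numbers 1, 2, 4, 5 and 6 occur in each group. The labels call them independent replicates and give each its own start day, so a number marks a shared day and pairs the libraries. In the data, deviations of same-numbered libraries from their group means correlated at a median of 0.59, between 0.08 and 0.64, with 14 of 15 pairs over 0.1. The median for libraries of different numbers was -0.16, and 13 of 15 libraries correlated best with a library of their own number. No pair of the 15 libraries differed by counting error alone, since the chi-square per degree of freedom over all pairs lay between 2.11 and 17.1.

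The comparisons, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The chosen test, edgeR with TMM factors, had assumed counts, and limma was its stated replacement for other values. Because the deposited values were CPM, the main test became limma 3.58.1 in R 4.3.3 on log2(CPM + 0.5), with trended and robust variance moderation, all 15 libraries and the group as only term, which left 12 residual degrees of freedom. The fit with the replicate number as a block, which left 8, had been chosen as an alternative beforehand and is given beside the main result wherever it changed a call. The main fit ignores the pairing and leaves differences between replicate numbers in its residual spread. They also enter the inter-gene correlations that were estimated without the block. P values were adjusted by the Benjamini-Hochberg method over all 14379 genes, with a threshold of 0.05. Fold changes are differences on the log2(CPM + 0.5) scale, which understates the change of genes near 0.5 CPM. No gene was filtered out.

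Up to 10 genes per direction and comparison were named. They had an adjusted p under 0.05, a mean log2 CPM of at least 1 and the same direction in all 5 replicate numbers, ranked by fold change. Where the main test gave fewer than 10, genes of the blocked fit filled the list. For each gene list described, up to 4 members with the lowest p were eligible, together with members needed to describe a small count. A further 12 genes were fixed by name. Some genes that met these rules are not described here.

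Of 38 gene lists, 35 had at least 5 measured members and were tested with camera in limma, with an inter-gene correlation preset at 0.01, adjusted over the 35 lists of a comparison. The same lists were tested with an estimated correlation, with fry, and, as an addition made after the data were seen, with an exact permutation of the 3 group labels within replicate numbers. That permutation has 7776 arrangements, and 0.00026 is the smallest p they can give. Lists were described where the preset test passed in either fit or at least 3 members passed the gene test.

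Alternatives chosen beforehand were DESeq2 1.42.0 on the recovered reads, RLE factors in limma and edgeR, and a filter of 1 CPM in at least 5 libraries. Fits on the 2 groups compared, and leaving out each library or replicate number, were also chosen beforehand. Alternatives added after the data were seen were edgeR 4.0.16 with TMM factors on the recovered reads, TMM factors in limma, and pseudocounts of 0.1 and 1. Added likewise were leaving out libraries or replicate numbers in the blocked fit, and correction for GC content and transcript length (from GENCODE 29, 13803 genes). So were thinning to equal depth, the mean of the mesenchymal-type markers as a covariate, and leaving out libraries with surfactant reads. Gene coordinates came from a RefSeq table for GRCh38.p14, matched on current and older symbols.

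The test was tried on simulated data for ethanol versus control with 14379 genes, 50 of them changed at each of 4 fold sizes. The main fit recovered 8%, 56%, 78% and 92% of the genes changed 1.1, 1.2, 1.5 and 2-fold, with 0% false calls. With the block, 34%, 72%, 92% and 100% were recovered and 3.25% of calls were false. Neither fit called a gene in a simulated comparison without change. The simulated noise was independent between libraries and genes, so these rates do not cover differences within a replicate number that many genes share. In the real data, among 16 blocked exchanges within withdrawal and control pairs, the highest count was 224 genes.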

Results

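The series compared SH-SY5Y neuroblastoma cells, which have noradrenergic neuron-like features, after repeated ethanol exposure with untreated cells and with cells withdrawn from ethanol. Exposure was to 40 mM ethanol for 4 h a day on 4 days a week over 3 weeks. The 5 ethanol cultures were collected at the end of the last exposure. The 5 withdrawal cultures had 24 h without ethanol, and so had 3 rather than 4 exposure days in the last week. The withdrawal group therefore differs from the ethanol group both in the time since exposure and in the number of exposures. Each replicate number (1, 2, 4, 5 and 6) supplied 1 control, 1 ethanol and 1 withdrawal culture. Expression of all genes in the deposited table was compared as CPM with limma, and means are given with SD (n = 5 per group) unless SE is named.

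Genes of the mesenchymal-type state of neuroblastoma differed between cultures by replicate number. Their list was not called for ethanol against control, except with the block and without replicate number 6 (camera with limma, 0.027). TAGLN, which encodes an actin-binding protein of contractile cells, had means of 7.93, 13.2, 34.9, 70.7 and 96.2 CPM over replicate numbers 1, 2, 4, 5 and 6 (adjusted p = 3.9e-11 for replicate number, limma). CAVIN1, a coat protein of caveolae, ranged from 3.39 to 28.2 CPM, ACTA2 from 6.55 to 48.5, the collagen gene COL3A1 from 19.5 to 128, CD44 from 3.02 to 14 and fibronectin (FN1) from 203 to 648. Of 23 mesenchymal-type markers 22 differed between replicate numbers, and their mean ran from -0.49 log2 units in number 1 to 0.50 in number 5. The adrenergic markers, which belong to the opposite state, moved the other way over a narrower range, from 0.08 to -0.09, with 17 of 21 differing. In all, 4390 genes differed between replicate numbers in limma. Component 1 held 47.7% of the variance of the libraries, and 98.9% of it was explained by replicate number. Components 2 and 3 held 8.17% and 6.25%.

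**Figure D1:**
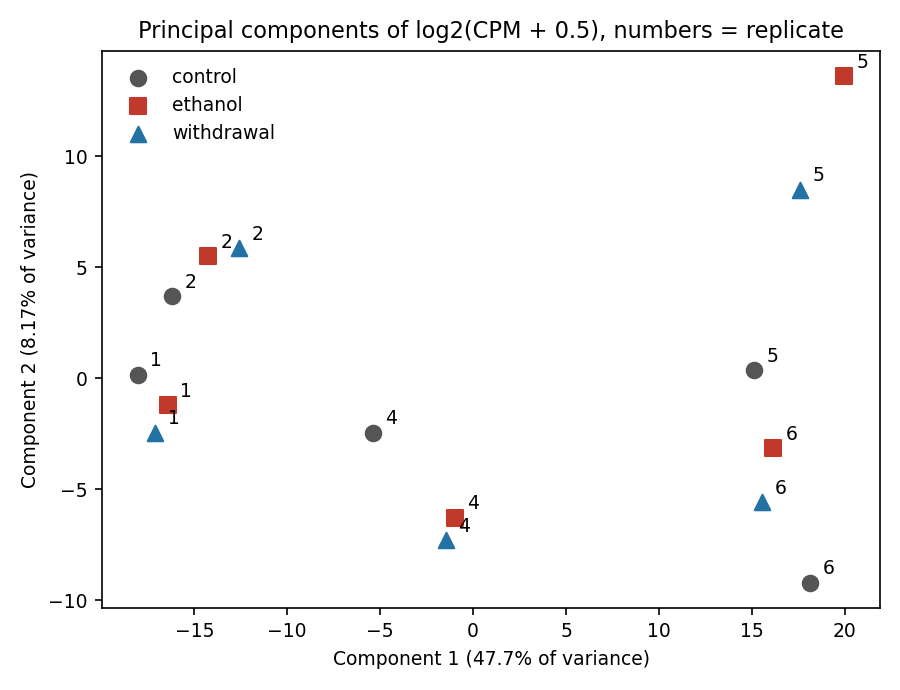
Principal components of the 15 libraries, with the group shown by symbol and the replicate number beside each point. Libraries of the same replicate number lie together along component 1.

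In ethanol-exposed cells, SLC16A14, an orphan member of the monocarboxylate transporter family (chromosome 2, 230034982 to 230068924), rose from 8.96 ± 0.786 to 13.7 ± 0.572 CPM (log2 fold change 0.59, SE 0.084, adjusted p = 0.0065). Its relative SLC16A9, also a monocarboxylate transporter family gene, rose from 26.4 ± 0.597 to 33.8 ± 1.65 CPM (0.35, SE 0.05, 0.0065). MGEA5, now named OGA, encodes the enzyme that removes O-linked N-acetylglucosamine from proteins, and rose from 128 ± 7.38 to 162 ± 7.21 CPM (0.34, SE 0.046, 0.0065; chromosome 10, 101784450 to 101818444). The arrestin-domain gene ARRDC3, whose product controls turnover of membrane receptors, rose from 75.1 ± 2.79 to 91.1 ± 3.57 CPM (0.28, SE 0.043, 0.012; chromosome 5, 91368631 to 91383317). ODC1, which encodes the first enzyme of polyamine synthesis, rose from 274 ± 13 to 327 ± 12.1 CPM (0.26, SE 0.045, 0.035; chromosome 2, 10439968 to 10448327).

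The zinc-finger gene ZNF844 rose from 8.94 ± 0.918 to 12.4 ± 0.679 CPM (0.45, adjusted p = 0.034), the Wnt coactivator gene BCL9L from 69 ± 3.53 to 79.8 ± 2.72 (0.21, 0.049) and CMTM4 from 64.3 ± 1.72 to 74.2 ± 1.26 (0.21, 0.021). The genes that fell were C4orf3, which encodes a small regulator of the endoplasmic reticulum calcium pump, from 58.1 ± 1.77 to 50.2 ± 1.94 CPM (-0.21, SE 0.039, adjusted p = 0.045), and RSRC2 from 96.9 ± 2.45 to 85 ± 1.69 (-0.19, SE 0.034, 0.04). These 8 higher and 2 lower genes were all that limma called, with the same direction in all 5 replicate numbers, and with the replicate number as a block their adjusted p lay between 2.3e-07 and 0.0035. Without a block DESeq2 called 16 higher and 24 lower genes and edgeR 9 in all. With the block limma called 292 higher and 127 lower genes, edgeR 165 and 166, and DESeq2 83 and 100. With TMM factors the blocked limma split became 166 higher and 173 lower, with RLE factors 170 and 168, and after correction for GC content and length 181 and 414. The share of higher genes therefore depends on the scaling, while each of the 419 genes kept its sign in TMM, RLE, edgeR, DESeq2 and thinned data. Without the block, leaving out a library left between 3 and 7 genes, and leaving out a replicate number between 0 and 3. With the block, leaving out a library left between 160 (without control 2) and 416 (without control 6), and without replicate number 1 there were 112.

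Further genes passed only with the block. GPRC5C, an orphan receptor induced by retinoic acid, rose from 1.96 ± 0.365 to 3.35 ± 0.408 CPM (0.65, blocked SE 0.12, blocked adjusted p = 0.0025). SERTM2, a gene for a small membrane protein on chromosome X (111511645 to 111522399), fell from 43 ± 9.92 to 33 ± 8.34 CPM (-0.38, blocked SE 0.044, 7.4e-06). ZNF433 rose from 3.15 to 4.81 CPM (0.55, 0.0033). It lies next to its paralog ZNF844 on chromosome 19, so reads shared by the pair cannot be excluded. All of these, and the 10 genes above, stayed called in the blocked fit without any single library. ABHD11, a mitochondrial hydrolase gene, fell from 9.95 to 7.76 CPM (-0.34, 0.013) but lost its call without 2 of 10 libraries (up to 0.065). The noncoding or pseudogene loci MYLK-AS1 (-0.40, 0.048), RPL21P28 (-0.36, 0.046), CMAHP (-0.33, 0.044), MIR4458HG (-0.33, 0.018), EXOC3-AS1 (-0.33, 0.022) and ROR1-AS1 (-0.31, 0.05) also fell in the blocked limma fit. Each lost its call without 4 or more of 10 libraries, DESeq2 with the block called only MIR4458HG of them (0.036), and as antisense or pseudogene loci they may hold reads of other genes.

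Genes of the endoplasmic reticulum protein-folding machinery were higher in ethanol-exposed cells. HSPA5, the main chaperone of that compartment, had 276 ± 30.9 CPM in control and 305 ± 35.6 in ethanol, and rose in the blocked fit (0.14, blocked SE 0.023, adjusted p = 0.00051). PDIA4, a protein disulfide isomerase, rose from 215 to 232 CPM (0.11, 0.0097) and the stress transcription factor gene XBP1 from 64.3 to 70.3 (0.13, 0.032) in the same fit. The median of 23 chaperone and unfolded-protein-response genes was 0.07 higher, and their mean was higher in all 5 replicate numbers (0.08 ± 0.017). The list passed in camera with limma without a block (adjusted p = 0.0041; adjusted p = 0.89 with an estimated correlation) and with it (1.3e-06; adjusted p = 0.039 with an estimated correlation), and the exact permutation gave 0.009. In the blocked fit 3 members rose by the all-gene criterion and 10 when adjusted over the list alone, and edgeR with the block called 2. HSPA5 and PDIA4 kept their calls without any single library, and XBP1 lost its call without 7 of 10 (up to 0.16).

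Of 25 targets of the stress factor ATF4, 6 rose under ethanol in the blocked limma fit. SLC7A5, the large neutral amino acid transporter, rose from 89.8 ± 9.58 to 105 ± 12.3 CPM (0.22, adjusted p = 0.00025) and its partner SLC3A2 by 0.15 (0.038). SESN2, a stress-induced inhibitor of the growth kinase mTORC1, rose from 10.7 to 13.1 CPM (0.28, 0.016), CEBPB from 7.86 to 9.87 (0.31, 0.032), PHGDH from 106 to 115 (0.12, 0.028) and SLC7A1 by 0.10 (0.036). The median of 25 ATF4 targets was 0.06 higher (adjusted p = 0.013 in camera with limma without a block, adjusted p = 0.59 with an estimated correlation). The blocked value was 0.0043 (adjusted p = 0.27 with an estimated correlation), the exact permutation gave 0.098, and without replicate number 5 the blocked value was 0.063. Adjusted over the list alone 8 members rose, and edgeR with the block called 3, without PHGDH (0.06), SLC3A2 (0.06) and SLC7A1 (0.1). SLC7A5 kept its call without any single library, SESN2 lost it without 4 of 10, PHGDH without 6, and CEBPB, SLC3A2 and SLC7A1 without 7.

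Genes of cholesterol synthesis and uptake were lower under ethanol. HMGCS1, which encodes the enzyme that makes the precursor HMG-CoA, fell from 94.9 ± 9.68 to 80.6 ± 6.83 CPM in the blocked fit (-0.23, blocked SE 0.038, adjusted p = 0.00071). The synthesis genes IDI1 (-0.14), MSMO1 (-0.16), EBP (-0.18, 0.046) and SQLE (-0.11, 0.05) fell in the same fit, in which 7 of 23 members were called. The median of 23 genes was 0.08 lower and the mean was lower in each replicate number (-0.08 ± 0.017). Camera with limma gave 1.1e-08 without a block (adjusted p = 0.35 with an estimated correlation), 8.9e-11 with it (adjusted p = 0.047 with an estimated correlation) and the exact permutation 0.021. Adjusted over the list alone, 5 members fell without the block and 11 with it. HMGCS1 kept its call without any single library, IDI1 lost it without 5 of 10, MSMO1 and SQLE without 8 and EBP without 9.

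Genes of DNA replication, glycolysis and the hypoxia response also had lower values under ethanol. In the blocked fit MCM4, a subunit of the replicative helicase, fell from 383 ± 14 to 356 ± 14 CPM (-0.11, adjusted p = 0.009), with MCM7 (-0.08, 0.035) and UHRF1 (-0.11, 0.047). Hexokinase 2 (HK2), the entry enzyme of glycolysis, fell from 205 ± 7.24 to 182 ± 9.82 CPM (-0.17, blocked SE 0.026, 0.00025) and LDHA, which makes lactate, from 940 ± 31.5 to 866 ± 56.2 (-0.12, 0.0023). The HIF targets PFKFB3 (132 ± 5.77 to 116 ± 9.51 CPM, -0.19, 0.00071), BNIP3 (109 to 97 CPM, -0.17, 0.0064), PDK1 (-0.12, 0.032) and PPFIA4 (-0.20, 0.048) fell in that fit. Among neuronal cytoskeleton genes, STMN2 fell from 1530 ± 108 to 1430 ± 59.7 CPM (-0.10, 0.024) and DCX from 629 to 592 (-0.09, 0.043). ENO2, a neuronal enolase that is also a glycolysis gene, fell from 197 to 184 (-0.10, 0.023). MCM4, HK2, LDHA, PFKFB3 and BNIP3 kept their calls without any single library. STMN2 lost its call without 5 of 10 libraries, ENO2 and PDK1 without 6, MCM7, UHRF1 and DCX without 8, and PPFIA4 without 9. PDK1 also lost its call after correction for GC content (0.27).

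For S-phase genes the median over 31 members was -0.06, with camera in limma at 6e-09 without and 8.9e-11 with the block (adjusted p = 0.12 with an estimated correlation and the block; exact permutation 0.027). Glycolysis (19 members, -0.04) had 1.1e-06 and 4.5e-08 (adjusted p = 0.27 with an estimated correlation and the block; exact permutation 0.082). HIF targets (25 members, -0.08) had 3.8e-05 and 1.3e-07 (adjusted p = 0.12 with an estimated correlation and the block; exact permutation 0.065). The neuronal cytoskeleton list (23 members, -0.03) had 0.0025 and 6.1e-05 (adjusted p = 0.047 with an estimated correlation and the block; exact permutation 0.021). Without a block none of the 10 lists called kept its call with an estimated correlation, where the lowest adjusted p was 0.35. Adjusted over each list alone 11 S-phase, 5 glycolysis, 5 HIF and 3 neuronal genes fell with the block. These lists, the cholesterol list and the chaperone list kept their blocked calls and directions under TMM factors, correction for GC content, and the loss of any replicate number.

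**Figure D2:**
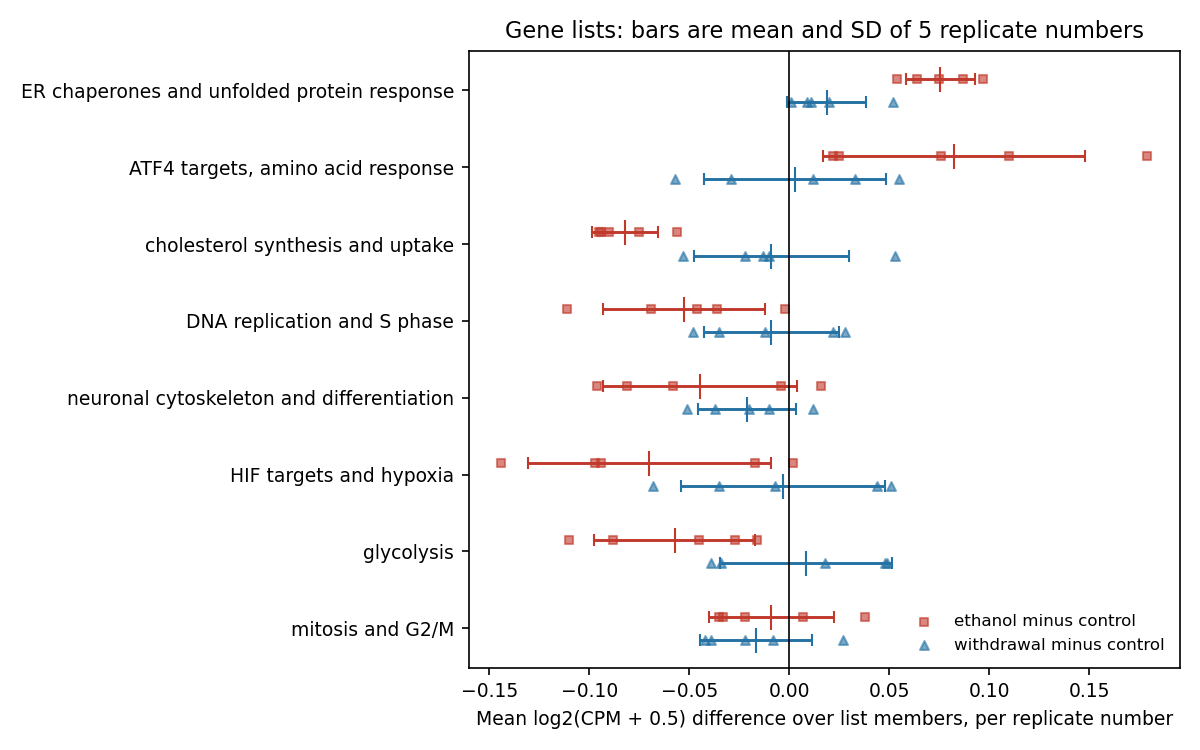
Mean log2 difference from control of 8 gene lists in each replicate number, for ethanol (red) and withdrawal (blue), with mean and SD. Except for the mitosis list, the means of withdrawal lay nearer to 0 than those of ethanol.

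Other groups shifted under ethanol in fewer settings. The pacemaker channel gene HCN2 rose in the blocked fit (0.18, adjusted p = 0.046), while the calcium channel subunit gene CACNA2D2 fell (-0.10, 0.041). SMAD6, an inhibitor of BMP signalling, rose from 37 to 45.4 CPM (0.30, 0.00015) and ID1 from 88.9 to 99.7 (0.16, 0.013). The plexin genes PLXNA1 (240 to 264 CPM, 0.13, 0.0023) and PLXNA2 (489 to 525, 0.11, 0.0069) rose and the ephrin gene EFNB2 fell (85.1 to 76.3, -0.16, 0.0081). LAMC1 rose by 0.11 (0.044), and the histone gene HIST2H2BE fell from 7.35 to 5.92 CPM (-0.30, 0.035). SMAD6, PLXNA1 and PLXNA2 kept these calls without any single library, while EFNB2 lost its call without control 2 (0.061), ID1 without 4 of 10 libraries, HCN2 and CACNA2D2 without 7, and LAMC1 and HIST2H2BE without 8. Correction for GC content ended the calls of PLXNA1 (0.081), PLXNA2 (0.27), HCN2 (0.19) and LAMC1 (0.11), and TMM factors those of HCN2 (0.073) and LAMC1 (0.1).

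Their lists passed in camera with limma with the block only: ion channels 0.0066 (adjusted p = 0.4 with an estimated correlation), TGF-beta and BMP genes 0.0077 (adjusted p = 0.39 with an estimated correlation), axon guidance 0.017 (adjusted p = 0.71 with an estimated correlation) and extracellular matrix 0.044 (adjusted p = 0.73 with an estimated correlation). Histone genes passed without a block (0.024) and with it (0.04; adjusted p = 0.2 with an estimated correlation), but not with TMM factors (0.093). Correction for GC content ended the blocked calls of ion channels (0.065), axon guidance (0.26), extracellular matrix (0.43), histones (0.32) and oxidative phosphorylation (0.063), and TMM factors also that of extracellular matrix (0.051). With the mesenchymal-type mean as covariate TGF-beta and BMP genes had 0.14, axon guidance 0.19, extracellular matrix 0.88, histones 0.086 and oxidative phosphorylation 0.23, while ion channels still passed. The matrix list shares members such as FN1 with that covariate, so its value there carries less weight. Ribosomal proteins, median -0.02, had 0.022 and 8e-05 (adjusted p = 0.73 with an estimated correlation), and oxidative phosphorylation genes, median -0.02, had 0.038 and 0.029 (adjusted p = 0.75 with an estimated correlation). limma called no member of either in the blocked fit, edgeR with the block called the ribosomal gene RPS27 as lower (0.043; 0.036 in limma with TMM factors), and without replicate number 4 their blocked values were 0.67 and 0.91.

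The noradrenergic genes moved individually, without a shift of the group. In the blocked fit DBH, the enzyme that makes noradrenaline, rose from 828 ± 47.1 to 900 ± 45.1 CPM (0.12, adjusted p = 0.0046), and the noradrenaline transporter gene SLC6A2 from 267 ± 31.2 to 296 ± 33.7 (0.15, 0.00036). PHOX2A rose from 580 to 630 CPM (0.12, 0.023) and SOX11 from 611 to 683 (0.16, 0.03), while TFAP2B fell from 688 to 632 (-0.13, 0.0053), DDC from 125 to 115 (-0.11, 0.026) and SCG2 by 0.12 (0.028). DBH, SLC6A2 and TFAP2B kept their calls without any single library, SOX11 lost it without 4 of 10, PHOX2A and DDC without 6 and SCG2 without 7. PHOX2A and SOX11 were not called by edgeR with the block (0.054 and 0.064) or by limma with TMM factors (0.055 and 0.069). The adrenergic and catecholamine lists had blocked camera values of 0.59 and 0.64 in limma.

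Genes that handle ethanol and acetaldehyde had similar means in both groups and were not called. ADH5 had 153 ± 6.54 CPM against 153 ± 10.9 in control, ALDH2 75.6 ± 3.46 against 75 ± 3.16, CAT 40.8 ± 2.92 against 41 ± 3.11 and ACSS2, which makes acetyl-CoA from acetate, 23.1 ± 0.844 against 23 ± 2.11. CDK1 (122 against 126 CPM), VEGFA (115 against 116), VIM (936 ± 101 against 922 ± 93.7) and HMOX1 (0.56 against 0.451) were not called by limma in either fit, with blocked adjusted p of at least 0.21. No shift passed in camera with limma for alcohol metabolism (0.29 with the block), fatty acid synthesis (0.29), mitosis (0.092), p53 targets (0.23), NRF2 targets (0.67), heat shock (0.31), interferon (0.45), NF-kB targets (0.81) or circadian genes (0.21). Nor did it for immediate early genes (0.99), synaptic genes (0.88), ionotropic receptors (0.99), mesenchymal-type (0.75), fibroblast (0.95), Schwann-cell (0.88) and epithelial (0.12) markers, integrins (0.75), Wnt and Notch genes (0.19) or enzymes acting on DNA and histones (0.88). Reads of the lung surfactant gene SFTPC were counted in all 15 libraries, with 229 CPM in ethanol 5, 48.9 in withdrawal 2 and a median of 1.83.

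Cells withdrawn from ethanol for 24 h had no gene called different from control. Genes raised by ethanol and called lower in withdrawal than in ethanol without the block were near control values. They were SLC16A14 at 8.49 ± 1.17 CPM (control 8.96), ARRDC3 at 73.4 ± 4.43 (75.1), ODC1 at 269 ± 18.3 (274) and MGEA5 at 133 ± 7.99 (128). Their choice rests partly on that second call, which favours values near control. HSPA5 had 280 ± 29.1 CPM (276), ACSS2 25 ± 1.82 (23), ADH5 152 ± 4.8 (153), ALDH2 74.9 ± 1.89 (75) and CDK1 119 (126). limma called 0 genes, with 246 at unadjusted p under 0.05 without the block and 757 with it. edgeR called 0 (241 and 750) and DESeq2 0 (165 and 285). With the block 7 genes were called without control 6 and 3 without replicate number 6.

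Shifts of gene groups in withdrawal against control depended on the block or the scaling. Extracellular matrix genes were higher in 29 of 31 members (median 0.08; LAMA1 49.4 against 45.7 CPM, COL4A2 337 against 318; camera with limma 2.5e-09). TGF-beta and BMP genes had a median of 0.06 (0.00049), axon guidance 0.04 (0.0016), p53 targets 0.05 (0.018) and mesenchymal-type markers 0.05 (0.038). Ribosomal protein genes were lower in 34 of 35 members (median -0.03, 1.4e-05) and mitosis genes had -0.02 (0.047). No member of these lists was called by the all-gene criterion, and fry called 0 lists in this comparison with or without the block. For every list adjusted p was at least 0.66 with an estimated correlation and at least 0.83 in the exact permutation, and without the block the matrix and axon guidance lists had 0.051 each (0.048 with TMM factors), the lowest of all lists. With the mesenchymal-type mean as covariate p53 targets still passed (0.045), the matrix and ribosomal lists had 0.066 each, TGF-beta and BMP genes 0.24, axon guidance 0.31 and mitosis 0.46. For the matrix list, which shares members such as FN1 with the covariate, this value carries less weight. Correction for GC content ended the calls of axon guidance (0.13), mitosis (0.41) and the mesenchymal-type list (0.054).

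Compared with ethanol-exposed cells, withdrawn cells had lower values of the genes that ethanol had raised. SLC16A14 fell from 13.7 ± 0.572 to 8.49 ± 1.17 CPM (-0.67, SE 0.084, adjusted p = 0.0029), ARRDC3 from 91.1 ± 3.57 to 73.4 ± 4.43 (-0.31, 0.005), ODC1 from 327 ± 12.1 to 269 ± 18.3 (-0.29, 0.019) and MGEA5 from 162 ± 7.21 to 133 ± 7.99 (-0.28, 0.023). These 4 were all that limma called without the block, and DESeq2 called 34 higher and 18 lower. With the block limma called 128 higher and 188 lower genes, edgeR 189 and 113, and DESeq2 133 and 43. TMM factors gave 186 and 108 and correction for GC content 334 and 158, so the share of higher genes again depends on the scaling. Without the block, leaving out a library left between 2 and 4 genes, and leaving out a replicate number between 0 and 5. With the block, leaving out a library left between 84 (without ethanol 5) and 236 (without withdrawal 2).

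**Figure D3:**
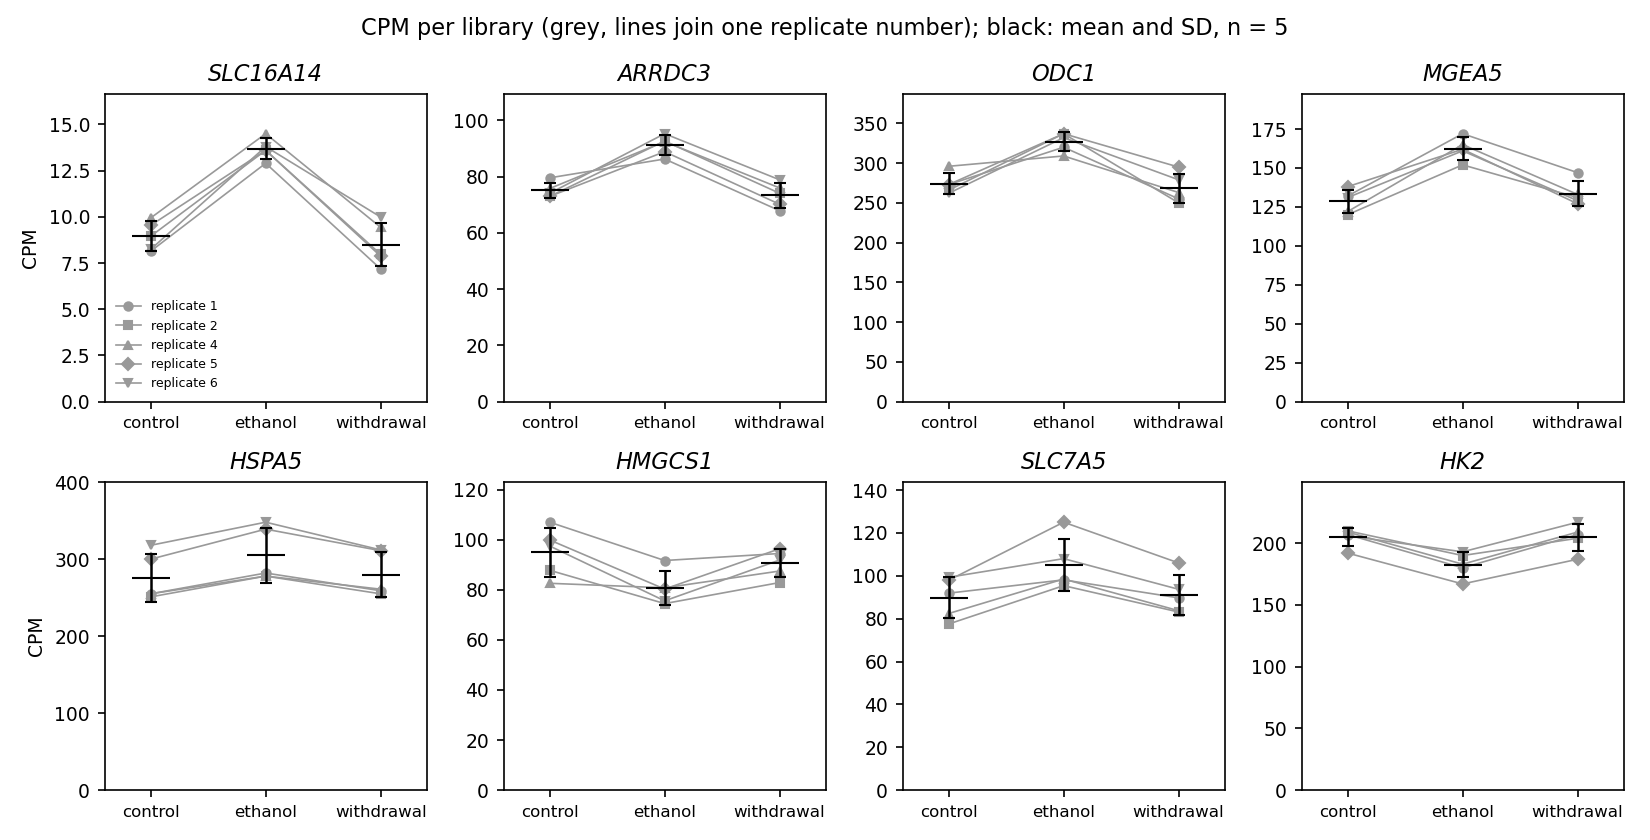
CPM of 8 genes in each library, joined by replicate number, with mean and SD per group. Shown are SLC16A14, ARRDC3, ODC1, MGEA5, HSPA5, HMGCS1, SLC7A5 and HK2.

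In the blocked fit the imprinted gene RTL1 rose from 186 ± 16.3 to 229 ± 18.5 CPM on withdrawal (0.30, adjusted p = 0.00017), SPRY1, an inhibitor of growth factor signalling, from 11.1 to 14.4 (0.36, 0.0056) and the noncoding locus TSPEAR-AS1 from 121 ± 18.3 to 152 ± 27.3 (0.33, 0.00017). HGFAC, which encodes the activator of hepatocyte growth factor, fell from 5.82 to 4.08 CPM (-0.47, 0.0085) and ZNF844 from 12.4 to 9.22 (-0.40, 0.0014). These stayed called without any single library.

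Other blocked calls of this size depended on single libraries. Higher were ANKRD1 (6.87 ± 6.74 to 9.29 ± 8.77 CPM, 0.45, blocked adjusted p = 0.016 in limma), THBS1 (18.5 to 23.1, 0.34, 0.01), EHD2 (0.35, 0.031), ATG16L2 (7.2 to 9.08, 0.31, 0.027) and PEAR1 (0.31, 0.016). Lower were ZNF433 (-0.45, 0.019), LINC00473 (6.42 to 4.62, -0.44, 0.014), KCNC4 (5.63 to 4.08, -0.42, 0.018) and ZNF488 (-0.41, 0.029). THBS1 lost its call only without withdrawal 4 (0.056), ANKRD1 without 6 of 10 libraries, EHD2 and ATG16L2 without 8, ZNF488 without 7, ZNF433 and LINC00473 without 4, KCNC4 without 3 and PEAR1 without 2.

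Metabolic and replication genes had higher values in withdrawn than in ethanol-exposed cells. In the blocked fit HK2 rose to 205 ± 11.1 CPM (0.17, adjusted p = 0.00044), LDHA to 933 (0.11, 0.0082), ENO2 by 0.11 (0.018), PFKFB3 to 136 ± 9.47 (0.22, 0.00016), PPFIA4 by 0.25 (0.02) and HMGCS1 to 90.6 ± 5.46 (0.17, 0.015). MCM4 (0.09, 0.032), MCM7 (0.08) and UHRF1 (0.11) rose, as did the fatty acid synthesis genes SREBF1 (40.8 to 47.1 CPM, 0.21, 0.0051), SCD (527 to 566, 0.10, 0.014), FASN (811 to 867, 0.10, 0.022) and ACLY (0.08, 0.047). HSPA5 fell to 280 CPM (-0.12, 0.0033), SEL1L by 0.11 (0.032), SLC7A5 to 91.2 CPM (-0.20, 0.0014) and PSPH by 0.19 (0.043). Of the noradrenergic genes TFAP2B (0.12, 0.013) and RET (307 to 335 CPM, 0.13, 0.0062) rose and DBH (-0.11, 0.013), PHOX2A (-0.11, 0.033) and SOX11 (-0.15, 0.038) fell. HK2, PFKFB3, SREBF1, HSPA5, SLC7A5 and RET kept these calls without any single library. LDHA lost its call without 2 of 10 libraries, SCD and TFAP2B without 3, DBH without 4, HMGCS1 without 5, ENO2 and PPFIA4 without 6, and FASN and PHOX2A without 7. UHRF1, SOX11 and PSPH lost it without 8, MCM4, MCM7 and SEL1L without 9, and ACLY without each of the 10. edgeR with the block did not call PSPH (0.059), SEL1L (0.063), PHOX2A (0.068) or SOX11 (0.072).

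Camera with limma called glycolysis (3.9e-09 without, 7e-11 with the block; adjusted p = 0.19 with an estimated correlation), cholesterol synthesis (7.4e-07, 8e-09; adjusted p = 0.1 with an estimated correlation), S phase (7.4e-07, 1.6e-08; adjusted p = 0.19 with an estimated correlation), HIF targets (0.00019, 1.1e-06; adjusted p = 0.17 with an estimated correlation) and the neuronal cytoskeleton (0.038, 0.0011; adjusted p = 0.11 with an estimated correlation) as higher. It called ATF4 targets (0.025, 0.007; adjusted p = 0.34 with an estimated correlation) and chaperones (0.047, 0.00042; adjusted p = 0.1 with an estimated correlation) as lower. Fatty acid synthesis passed with the block only (0.044; adjusted p = 0.54 with an estimated correlation). Without the block the lowest value with an estimated correlation was 0.4, and the lowest exact permutation value was 0.15. Adjusted over each list alone, 11 glycolysis, 11 cholesterol, 7 HIF and 6 S-phase genes rose and 7 ATF4 targets and 2 chaperones fell in the blocked fit.

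Part of the genes changed by ethanol changed back on withdrawal. Of the 10 genes called without a block, the 4 named above changed in the opposite direction on withdrawal (0.0022 would be shared by chance if the comparisons were independent). Of the 419 genes called with the block, 104 rose under ethanol and fell on withdrawal and 68 fell and then rose, and 0 moved further in the same direction. These comparisons share the ethanol libraries, which alone favours opposite signs. In replicate numbers not used to call them, ethanol-called genes changed by 0.13 ± 0.0401 under ethanol and by 0.01 ± 0.0351 in withdrawal (SD, n = 5 held-out numbers), which does not depend on the sharing of libraries for the choice of genes.

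Fold changes of ethanol and of withdrawal against the same controls correlated at 0.411 over 12800 genes (SE 0.0575, jackknife over replicate numbers). Simulated unchanged data with shared controls gave 0.5, a value set by the sharing, so a positive correlation arises without a shared effect. That simulation held no ethanol effect, which would lower its value, so 0.411 against 0.5 cannot decide whether part of the effect was kept. The check chosen beforehand, with only the controls split into disjoint sets, gave a median correlation of -0.213 (-0.629 to 0.0298). It leaves differences between replicate numbers in the control means, so it cannot decide either. With disjoint replicate numbers in both comparisons the median was 0.00735 (-0.153 to 0.0756). The slope corrected for noise was 0.0501 (SE 0.215), too wide to exclude a partly kept effect. The same sign was seen in 63.2% of genes against 66.7% in unchanged data, with the same limit.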

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

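The GC correction of the ethanol genes, the mesenchymal-type covariate, the correlation of the mesenchymal-type markers and the surfactant tests were chosen only after the results were seen, while the splits and, for component 1, the thinning and GC tests were written down before.

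That ethanol changed genes which changed back on withdrawal could reflect the treatment, uneven GC and length effects, or a differing share of mesenchymal-type cells. Genes called higher in 4 replicate numbers rose by 0.136 in the number left out and by 0.108 (SE 0.013) after correction for GC content and length, and genes called lower fell by 0.12 before and 0.151 (SE 0.022) after it, so that GC and length do not account for either. The correction did remove calls, since 172 of 287 higher genes stayed called and their median GC content was 52.7% against 48.4% for all genes. With the mesenchymal-type mean as covariate 94.9% of the median change of the higher genes and 97.2% of that of the lower genes remained, which speaks against that share as the cause. The covariate removed calls too, and 157 of 292 higher and 72 of 127 lower genes stayed called. A response to the last 4 h of exposure is a hypothesis that no test here separated from a reversible effect of the 3 weeks, from the extra exposure day or from handling, so these stay open.

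The separation by replicate number may stem from depth, from GC and length effects or from a varying share of mesenchymal-type cells. Component 1 held 45.9% of the variance after thinning to equal depth (47.7% before) and 49.8% after correction for GC content and length (49.3% before on the same genes), so neither accounts for it. The mesenchymal-type markers correlated with each other over replicate numbers at a median of 0.915, against a median of -0.00502 and a 95th percentile of 0.155 in 10000 random lists, and the adrenergic markers, of the opposite state, at 0.595. A varying share, or a varying degree, of these states fits the values, which largely restate that both sets of markers differ by replicate number, and bulk RNA cannot tell share from degree. Passage number, which was not given per library, is a further candidate that was not tested.

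Lung surfactant RNA in some libraries might come from lung epithelial material outside the culture, from a single source spread over the libraries, or from ethanol exposure. SFTPC had 4443 reads (229 CPM) in ethanol 5, 981 (48.9) in withdrawal 2, 482 (23.3) in withdrawal 5, 359 (16.3) in control 2 and 301 (13.1) in control 5, all in replicate numbers 2 and 5. Of 15 other lung markers listed, 6 were in the file, and all 6 were highest in ethanol 5. For ABCA3 this rank carries no weight, with 179 CPM in ethanol 5, 177 in control 5 and a median of 158. SFTPB, SFTPA1, SFTPA2, SFTPD and NAPSA had 5.82 to 28 CPM in ethanol 5, against medians of 0.284 to 0.582, which fits material of lung type. SFTPC was higher in ethanol than in control in only 2 of 5 replicate numbers, which speaks against ethanol. The ratio of SFTPB to SFTPC differed between 5 libraries (0.119, 0.21, 0.255, 0.237 and 0.0465; chi-square per degree of freedom 27.5), but this chi-square holds counting error only and no library was prepared repeatedly, so a single source stays open. Without ethanol 5 and withdrawal 2 the blocked limma fit called 152 genes for ethanol against control and 36 for withdrawal against ethanol, and without replicate numbers 2 and 5 it called 56 and 19.

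Splits of the 10 libraries of a comparison into other groups of 5, and blocked shuffles of the labels within replicate numbers, gave these results. For ethanol against control 1 of 100 blocked shuffles, the real one, called as many genes as the real 419 (highest other 170), so that chance can be excluded at 5 in 100 for the blocked count. Without the block 4 of 100 splits called as many as the real 10 (highest 2476), but 88 of the 99 others did not part all pairs as the real one does, so this share does not exclude chance among like splits. For withdrawal against ethanol 3 of 100 blocked shuffles, the real one among them, called as many as the real 316 (highest 457). That share is under 5 in 100, but it was not adjusted over the counts tested. Since another shuffle called more genes than the real one, chance is not clearly excluded for this count. Without the block 4 of 100 splits called as many as the real 4 genes (highest 962), with the same limit of unlike splits as above. The return held 172 genes, which 1 of 100 blocked shuffles reached (highest other 49). These shuffles also remove the ethanol effect, so few genes could count as returned in them. They therefore cannot tell a return from the opposite signs that the shared ethanol libraries favour. For withdrawal against control the real count was 0 in both fits, which 100 of 100 splits or shuffles must reach (highest 1646 and 142), so this test decides nothing there. The splits that called many genes left libraries of the same replicate number on the same side in at least 1 pair and point to sample structure. Among the 11 splits that part all 5 pairs, as the real one does, the highest was 0 genes in each comparison, and among 16 blocked exchanges within pairs it was 19 for ethanol against control, 224 for withdrawal against control and 0 for withdrawal against ethanol, and 11 or 16 are too few to show a share under 5 in 100.

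By a criterion for 1 value apart from the other 4 of its group, which chance meets in about 1 in 20 groups, 25 of 477 groups (5.24%) had such a value. In control these were RSRC2 in control 2 (101 CPM, others 95.3 to 96.3), HERPUD1 in control 2 (21.6, others 24.4 to 25.5), SDF2L1 in control 2 (5.81, others 7.85 to 8.62), HMOX1 in control 5 (1.05, others 0.194 to 0.416), EFNB2 in control 5 (77.5, others 85.8 to 88.5), HK2 in control 5 (192, others 206 to 210), UQCRB in control 4 (98.5, others 87.3 to 89.6) and INHBA in control 6 (9.6, others 6.04 to 6.98). In ethanol they were ROR1-AS1 in ethanol 6 (5.58, others 3.6 to 4.17), SLC3A2 in ethanol 5 (56.1, others 44.7 to 47.6), LTBP3 in ethanol 5 (108, others 100 to 102), EPHB2 in ethanol 5 (122, others 129 to 131), LMO1 in ethanol 5 (53.1, others 60 to 61), SFTPC in ethanol 5 (229, others 0.405 to 7.51), RPLP1 in ethanol 2 (1040, others 827 to 884), NOTCH3 in ethanol 2 (143, others 119 to 125), SYVN1 in ethanol 2 (68.6, others 60.5 to 62.8) and the depth of ethanol 2 (20.9 M reads, M for mega, others 19.3 to 19.7). In withdrawal they were MGEA5 in withdrawal 1 (147, others 127 to 133), HERPUD1 in withdrawal 1 (23.6, others 25.2 to 25.7), TSPEAR-AS1 in withdrawal 5 (104, others 158 to 170), SLC7A1 in withdrawal 2 (238, others 253 to 258), PFKFB3 in withdrawal 6 (152, others 130 to 136), AK4 in withdrawal 6 (59.8, others 46.3 to 49.9) and PFKP in withdrawal 6 (237, others 224 to 226).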

How the results depend on the processing

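Of the alternatives below, edgeR with TMM factors on recovered reads, the pseudocounts, TMM in limma and the GC correction were added only after the results were seen. So were thinning for the gene counts, the covariate, the leave-outs with the block and the removal of surfactant libraries. Before that, edgeR with TMM factors had been the chosen test for the case of deposited counts.

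The main limit is the replicate number, over which 4390 genes differed in limma. Without the block limma called 10 genes for ethanol against control and with it 419, and for withdrawal against ethanol 4 and 316, while the return held 4 genes and 172. The pairing rests on the labels and on the data. Counts without and with the block both depend on single libraries. For ethanol against control DESeq2 called 40 genes without and 183 with the block, and a fit on the 2 groups only called 5. With the block a fit on the 2 groups only called 181, the mesenchymal-type covariate 247, the removal of ethanol 5 and withdrawal 2, with most surfactant reads, 152 and the removal of replicate numbers 2 and 5 56. For withdrawal against ethanol DESeq2 called 52 without and 176 with the block. With the block the 2 groups only gave 511, the GC correction 492, the removal of ethanol 5 and withdrawal 2 36 and that of replicate numbers 2 and 5 19. The return held 20 genes in DESeq2, 88 in DESeq2 with the block, 2 with RLE factors and 2 in edgeR with RLE factors. The DESeq2 values cover fewer genes, since DESeq2 gave no adjusted p value for the others. Leaving out 1 library or replicate number gave 0 to 7 genes for ethanol against control (112 to 416 with the block), 0 to 0 for withdrawal against control (0 to 7 with the block), 0 to 5 for withdrawal against ethanol (84 to 236 with the block), 0 to 4 for the return and 0.316 to 0.607 for the correlation of fold changes, ethanol and withdrawal versus the same controls. With the block ethanol against control had 186, 160, 378, 345 and 416 genes without control 1, 2, 4, 5 and 6, 202, 259, 263, 185 and 276 without ethanol 1, 2, 4, 5 and 6, and 112, 114, 272, 207 and 270 without replicate numbers 1, 2, 4, 5 and 6. With the block withdrawal against ethanol had 110, 224, 194, 84 and 184 genes without ethanol 1, 2, 4, 5 and 6, 136, 236, 112, 177 and 154 without withdrawal 1, 2, 4, 5 and 6, and 91, 146, 172, 113 and 130 without replicate numbers 1, 2, 4, 5 and 6. Among the named genes and called lists the direction turned in 2 results when libraries were left out in the fits without the block. When single libraries were left out with the block, 0 of 66 described genes called for ethanol against control changed sign. For withdrawal against ethanol it was 0 of 42, ANKRD1 among them. The values that follow are without the block. ANKRD1, withdrawal versus ethanol, lay between -0.058 without ethanol 1 (adjusted p = 0.998 in limma) and 0.968 without withdrawal 1. The oxidative phosphorylation list in ethanol against control lay between -0.04 without replicate number 2 and 0.014 without replicate number 4 (adjusted p = 0.917 in camera with limma). The mitosis list, not called for ethanol against control, passed in camera with the block and TMM factors (adjusted p = 0.03), RLE factors (0.031) or without replicate number 6 (0.0073). For the remaining settings the cause was not tested.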

Other observations

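The lists of CREB and FOXO targets used below were chosen only after the ethanol results were seen, though before these lists themselves were tested.

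Further genes of fixed groups changed under ethanol in the blocked limma fit although their groups did not. The synaptic vesicle gene SYT4 fell from 124 to 111 CPM (-0.18, blocked adjusted p = 0.0023) and rose on withdrawal to 122 (0.14 against ethanol, 0.0276). The integrin gene ITGB5 rose from 20.3 to 24.3 CPM (0.24, 0.00811) and the co-chaperone gene BAG3 from 7.4 to 9.45 (0.34, 0.0175), while the adhesion gene ALCAM fell from 345 to 321 (-0.10, 0.0177) and SCD from 565 to 527 (-0.10, 0.0131). ZNRF3 (0.12, 0.0448), NRARP (0.17, 0.0447) and SYN2 (0.20, 0.0441) passed in limma but not in edgeR with the block, and lost their calls without 9 of 10 libraries. On withdrawal against ethanol SMAD6 fell from 45.4 to 38.8 CPM (-0.22, 0.00562), and DNMT3A, a DNA methyltransferase gene, rose from 204 to 220 (0.11, 0.0126), as did ID4 (0.25, 0.0176), SLIT3 (0.10, 0.0196) and EFNB2 (0.14, 0.0282). SMAD6 kept its call, as did ITGB5 and SYT4 under ethanol, without any single library. BAG3, SCD, DNMT3A and ID4 lost theirs without 3 of 10 libraries, ALCAM without 4, SLIT3 without 6, SYT4 on withdrawal without 7 and EFNB2 without 8. The 4 measured metallothionein genes were too few to test, and had a median of 0.18 in ethanol against control and of -0.14 in withdrawal against ethanol.

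Targets of FOXO factors, which growth factor signalling restrains, were examined because growth-related lists were lower under ethanol. SESN3 rose from 43.9 to 52.1 CPM (0.25, blocked adjusted p = 0.0023, limma), FBXO32 from 9.12 to 11.7 (0.33, 0.009) and TXNIP, which limits glucose uptake, from 228 to 246 (0.12, 0.014), and on withdrawal SESN3 (-0.26, 0.0018), TXNIP (-0.11, 0.022) and ULK1 (-0.13, 0.037) fell while KLF6 rose (0.15, 0.037). SESN3 kept both calls without any single library, FBXO32 lost its call without control 1 (0.065), TXNIP without 5 of 10 libraries under ethanol and 7 on withdrawal, ULK1 without 7 and KLF6 without 10.

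The hypothesis that growth factor signalling was reduced at the end of exposure, so that FOXO targets could rise, had a list value of 0.0073 with the block in camera (26 of 28 genes measured, median 0.06, 21 above 0; adjusted p = 0.034 with an estimated correlation). It remains open, since without the block the value was 0.053 and the exact permutation p, here not adjusted over lists, was 0.064. On withdrawal against ethanol the list was lower in camera with the block (0.025), but did not pass with an estimated correlation (adjusted p = 0.066) or without the block (0.11). The unadjusted exact permutation p was 0.042, and 7 of the 35 tested lists also had such a p under 0.05 there. In withdrawal against control the camera value was 0.62.

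The hypothesis that genes higher in ethanol might follow cAMP signalling through CREB was raised by ethanol's known action on adenylyl cyclase. Its list had a value of 0.86 with the block in camera and an unadjusted exact permutation p of 0.79. Of 38 genes 26 were measured, with a median of 0.03 and 18 above 0. The median over all genes was 0.016, and camera placed the list on the lower side without a call. PDE4D rose from 13.6 to 15.9 CPM (0.22, 0.044, lost without 7 of 10 libraries) and SCG2 fell, so the list could not tell.

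For gene lists chance may account for the number called. Without a block 54 of 100 splits called as many as the real 10 lists for ethanol against control (highest other 24) and 67 of 100 as many as the real 7 for withdrawal against ethanol (highest 23). With blocked shuffles the values were 9 of 100 for the real 14 lists (highest 16), 58 for 7 (highest 16) and 42 for 8 (highest 20). For withdrawal against control without a block the real count was 0, which 100 of 100 splits must reach (highest 21), so this test decides nothing there. Chance cannot be excluded for the other counts, and single lists rest on their own exact permutation, which 4 passed for ethanol against control. Without the block fry called 0 lists in each comparison. With it, fry called 9 for ethanol against control (camera 14), 0 for withdrawal against control (camera 7) and 3 for withdrawal against ethanol (camera 8).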
